A study of Mus musculus with 9 samples.

How the data were processed

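Messenger RNA was sequenced from 9 libraries of mouse colon epithelium, 3 for each of 3 populations sorted by surface antigens. Per the labels' protocols, crypts were released from the colon of adult female C57BL/6J mice with EDTA and dissociated with DNase I and a collagenase. Dead cells, doublets and cells with leukocyte or endothelial antigens were gated out, and RNA was extracted with a kit for small cell numbers. The Lgr5-enriched population carried Epcam and Cd44 and lacked Kit, the goblet-enriched population carried Epcam, Cd44 and Kit, and the enterocyte-enriched population carried Epcam and high Cd66a, the product of Ceacam1, and lacked Cd44. Libraries were made with a stranded poly-A kit and sequenced on either of 2 instruments, single-end or paired-end, per the labels, which do not say which library went to which. Per the series text, replicates are from 3 independent mice. The p-values measure the spread between libraries, which may mix animal, sex and batch.

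The deposited table holds 1 log2 value per gene symbol and library for 24421 symbols, and 0 per-sample columns were left unused. The values show how they were made: the lowest is -1, values of 0 and above back-transform as powers of 2, and values below 0 become TPM (transcripts per 1000000) when 1 is added. After this the 9 columns each sum to 1000000, so the authors' values are log2(TPM) where TPM is at least 1 and TPM minus 1 below it. Cufflinks and the mm10 build are named in the submitters' processing notes, with no version. The aligner, the annotation and any filter on reads are not given in the sources used here, nor is whether counting used the strand, so overlapping antisense genes and near-identical paralogs are uncertain. TPM corrects for transcript length and sets the same total in every library, so a very abundant transcript in a library lowers all others there. Symbols were looked up in a gene name table and in RefSeq, and 23641 were found. Gene positions were taken from the GENCODE mouse annotation of the same build.

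Depth was recovered from the values. The TPM value of 1 read times gene length was constant within a library for short genes with a single exon, and dividing by it gave whole numbers of reads in all libraries for 18386 of the 18396 genes above 0 (99.95%; tolerance 1e-06 of a read, gene lengths up to 20000 bases tried). The reads are the smallest whole numbers that the values allow: a factor shared by a gene's length and all its reads cannot be seen, so the reads of a gene, and the depth summed from them, are lower bounds. The libraries held 11.2 to 26.8 M reads in genes (M, times 1000000). A read in a gene of 1 kb was worth 0.0958 to 0.208 TPM, which limits what can be read from values below about 1 TPM.

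The values were tested as log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend), with 1 mean per population over all 9 libraries and no further covariate. Genes with at least 1 TPM in at least 3 libraries were tested, 12888 in all, which removed 5508 genes above 0. The model had 6 residual and 3.21 prior degrees of freedom. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05 within a comparison. Fold changes from the model are on the log2(TPM + 1) scale, which understates the change of low genes. A gene was counted as highest in a population when it was called and at least 2-fold higher there than in each of the others. Values in TPM are given as mean ± SD over the 3 libraries of a population. The chosen design assumed FPKM, and the same test was used for TPM.

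The following were fixed before the data were examined: the comparisons, the tests, the alternatives named as such, 29 gene lists and the rule for named genes. The lists were sorting antigens, Lgr5 stem cell markers, Wnt/beta-catenin targets, S phase and DNA replication, G2/M and mitosis, goblet cell markers, deep crypt secretory markers, colonocyte markers, enteroendocrine markers, tuft cell markers, Paneth cell markers, leukocyte markers, stromal and endothelial markers, Notch receptors and targets, Notch ligands, secretory lineage transcription factors, ER (endoplasmic reticulum) folding and secretion machinery, mucin O-glycosylation enzymes, brush border, ion and water transport, oxidative phosphorylation, fatty acid oxidation and ketogenesis, cholesterol synthesis, ribosome biogenesis, interferon-stimulated genes, MHC class II presentation, BMP response, antimicrobial and barrier defence, and dissociation and immediate early genes. Each was compared with all other tested genes by camera in limma with a preset inter-gene correlation of 0.01. This needed at least 4 tested members, which 27 lists had, and p was adjusted over the 81 tests of the 3 comparisons. Each test was repeated with a correlation estimated from the libraries. The self-contained fry test, which asks only whether the members of a list moved on balance in the same direction, passed for 54 of the 81.

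Genes are named by rule: 17 control genes, the 5 largest rises and falls of each comparison among genes called with at least 5 TPM in the higher population and no overlap between libraries, up to 4 members of each list (3 in its more frequent direction and 1 in the other, or the 2 most abundant where none was called), and 8 genes per population among those highest there. Symbols matching fixed patterns for predicted and unnamed genes, small RNAs and antigen receptor segments were left out, and AF357359 matches none of these. Genes named outside the rule, chosen after their values were seen, are Rn45s, Xist and the 4 Y-linked genes in the report and those of the closing section.

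The tests were tried on simulated data in which nearly all genes were unchanged. Real recovery may be lower and false calls more frequent. For goblet-enriched against Lgr5-enriched, 64% of 100 genes changed 2-fold and 95% of 100 changed 4-fold were called among 12876 genes. For enterocyte-enriched against Lgr5-enriched, 62% of 100 and 87.9% of 99 were called among 12835 genes. For goblet-enriched against enterocyte-enriched, 59% of 100 and 97% of 100 were called among 12864 genes. In the same order, 9, 6 and 8 unchanged genes were called.

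Replicate numbers are shared across populations. Deviations from the population means correlated at 0.19 to 0.60 for the 9 same-number pairs of libraries and at -0.52 to 0.17 for the others, and all 9 libraries correlated best with their own number, so the numbers were taken to pair the samples. The sex-linked genes show that replicate 1 does not come from a single animal, so for that number the pairing may be a shared day or batch. The fit without the block is the main one, as chosen beforehand.

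Alternatives were other pseudocounts, filters and scalings, a replicate block, library weights, no trend, fits to the 6 libraries compared, each library and each replicate number left out, a stricter fold for genes highest in a population and, chosen after seeing the data, limma-voom on the recovered reads, TPM without the pre-ribosomal RNA Rn45s, median-of-ratios scaling with a replicate block, and an estimated correlation under a block or other scalings. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.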

Results

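Gene expression was measured in 3 sorted populations of the mouse colon epithelium, with 3 libraries each: Lgr5-enriched cells from the crypt bottom, where the stem cells lie, goblet-enriched cells also from the crypt bottom, and enterocyte-enriched cells from the crypt top. The recovered depth was 26.8, 12 and 13.8 M reads for Lgr5-enriched replicates 1 to 3. It was 14, 12.8 and 12.1 M reads for goblet-enriched replicates 1 to 3 and 11.2, 16 and 13 M reads for enterocyte-enriched replicates 1 to 3. The deepest library also held the most pre-ribosomal RNA: Rn45s took 11.15% of its reads and stood at 49046 TPM, against 2356 to 6009 TPM in the other 8 libraries. The design asks how the transcriptomes of the 3 populations differ.

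The populations separated on the first 2 principal components, which held 45.1% and 32.2% of the variance. Pearson's r across genes was 0.955 to 0.983 within a population and 0.826 to 0.920 between populations. The component holding 11.4% of the variance set replicate 1 of every population (scores 40.4, 33.4 and 30.4) apart from replicates 2 and 3 (-26.9 to -9.5). Expression of 8136 of 12888 genes differed among the 3 populations (limma moderated F test, adjusted p under the threshold), and 8645 did so without the 3 libraries of replicate 1. With 1 library per population, replicate 1 alone gave no value. The labels assign no library to an instrument, so whether replicate 1 differed in its run cannot be told from them.

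**Figure D1:**
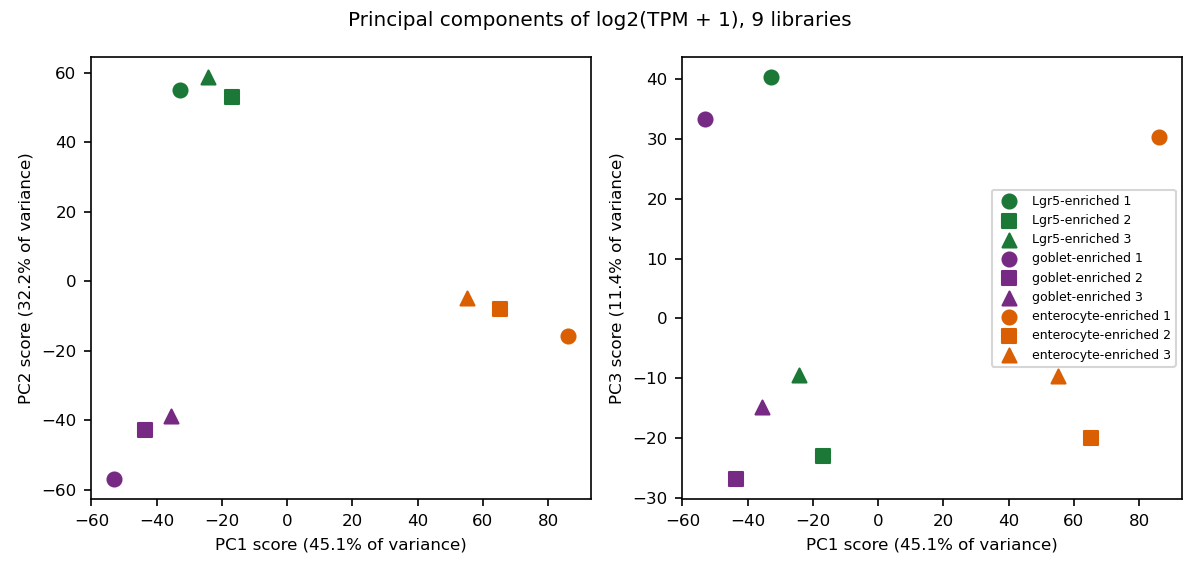
Scores of the 9 libraries on principal components 1, 2 and 3 of log2(TPM + 1), with the percent of variance on each axis and 1 point per library, coloured by population. Components 1 and 2 separate the populations, and component 3 separates replicate 1 (30.4 to 40.4) from replicates 2 and 3 (-26.9 to -9.5).

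The library labelled enterocyte-enriched replicate 1 differed from the other 8 libraries in its sex-linked transcripts. Xist, the RNA that silences an X chromosome in females (chromosome X, 103460366 to 103483254), stood at 0.13 TPM (11 reads) there and at 110.3 to 203.7 TPM elsewhere. The Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y stood at 22.51, 21.07, 14.33 and 80.70 TPM, a sum of 138.6 TPM from 1852 reads, whereas their sum was at most 0.32 TPM in any other library. The labels give female for all animals, so for this library the sex-linked values go against the label. Counts without it are given for each comparison that uses the enterocyte-enriched population.

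**Figure D2:**
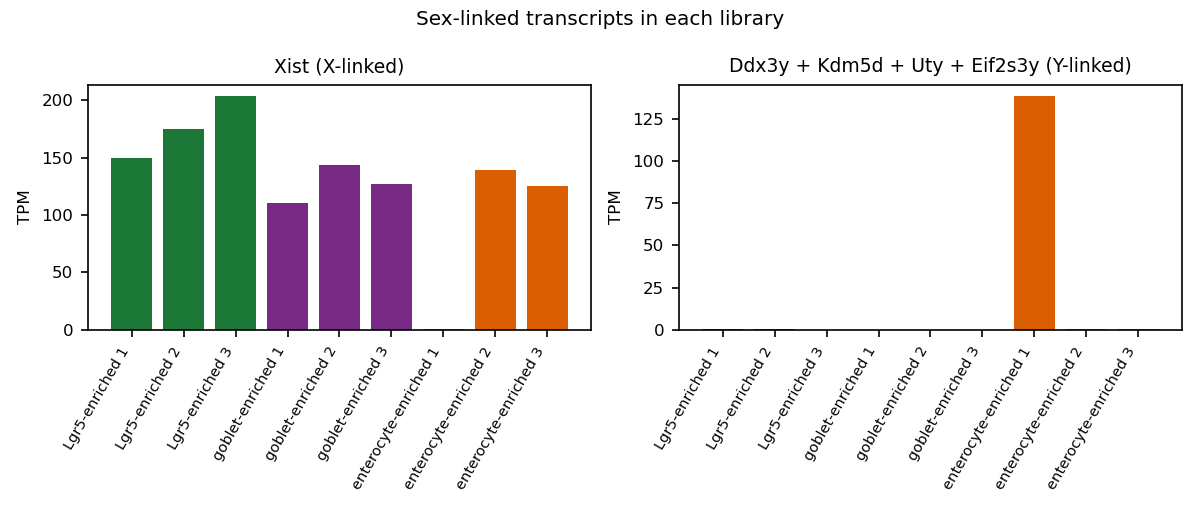
Bars give TPM per library, from 0, for Xist and for the sum of the Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y. The library labelled enterocyte-enriched replicate 1 has 0.13 TPM of Xist and 138.6 TPM of the Y-linked genes, and the other 8 have 110.3 to 203.7 TPM of Xist and at most 0.32 TPM of the Y-linked genes.

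The transcripts of the sorting antigens were compared first. Epcam (chromosome 17, 87635979 to 87651129, mm10), the epithelial adhesion antigen used for all gates, stood at 1866 ± 152, 1736 ± 209 and 1996 ± 71.6 TPM (SD, n = 3) in the Lgr5-enriched, goblet-enriched and enterocyte-enriched populations. It passed the limma test in none of the 3 comparisons. Under median-of-ratios scaling it was called higher in enterocyte-enriched against Lgr5-enriched (limma adjusted p = 0.0228; range over the alternatives 0.00937 to 0.987). Cd44 (chromosome 2, 102811141 to 102901665) stood at 75.6 ± 22.6, 26.0 ± 5.64 and 2.18 ± 0.788 TPM in the same order. Kit (chromosome 5, 75574916 to 75656722), the receptor that marked the goblet gate, stood at 8.90 ± 4.21, 202 ± 41.8 and 23.2 ± 5.53 TPM. Ceacam1 (chromosome 7, 25461707 to 25477603) stood at 1329 ± 79.5, 1767 ± 464 and 2715 ± 497 TPM. It was higher in the enterocyte-enriched than in the Lgr5-enriched population (log2 fold change 1.02, SE 0.21, limma adjusted p = 0.00394). It was also called against the goblet-enriched population (limma adjusted p = 0.0364; range 0.00227 to 0.22). That call ended without Lgr5-enriched replicate 2 or 3 (0.0522 and 0.0559), goblet-enriched replicate 2 or 3 (0.128 and 0.0989), or the libraries labelled enterocyte-enriched replicate 1 or 2 (0.0965 and 0.058). With all libraries kept it ended under quantile normalization (0.134), with no filter on low values (0.0885) and in the fit to the 6 libraries compared (0.0747). As a list, the 4 antigens passed no camera test (camera adjusted p = 0.262, 0.288 and 0.541 for goblet-enriched against Lgr5-enriched, enterocyte-enriched against Lgr5-enriched and goblet-enriched against enterocyte-enriched), while the self-contained fry test passed for the first and the last (adjusted p = 0.0182, 0.0605 and 0.00153). Since the gates chose cells by these antigens, they are no findings between the populations, and neither are Kit in the deep crypt secretory list, Ceacam1 in the colonocyte list and Cd44 in the Wnt list.

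**Figure D3:**
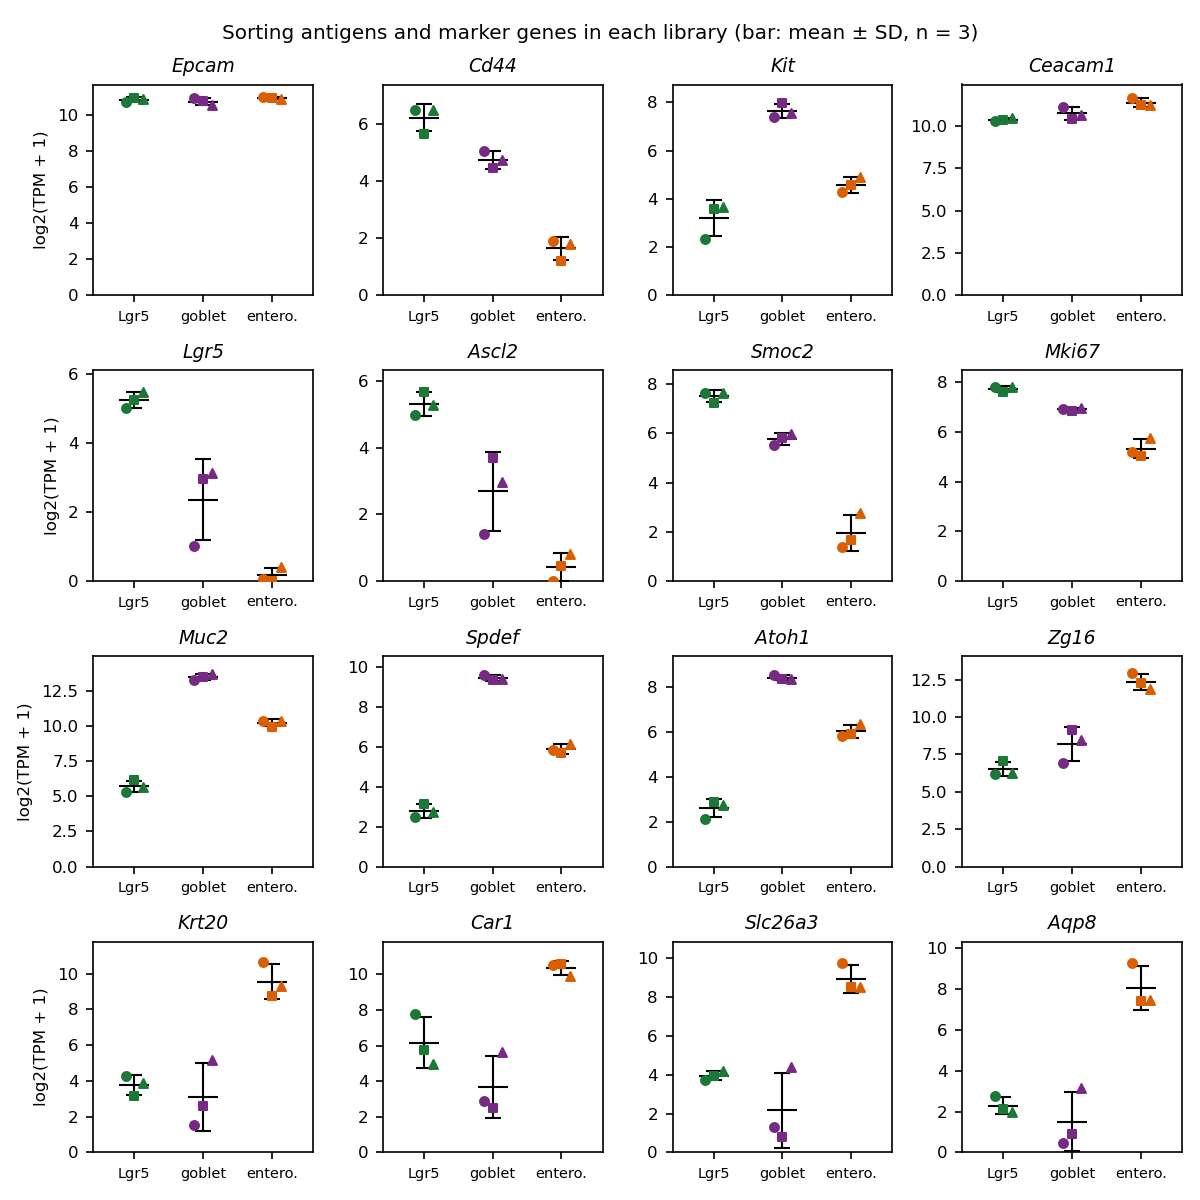
Levels of 16 genes as log2(TPM + 1), with 1 point per library, coloured by population, and bars for the mean ± SD (n = 3). Lgr5, Ascl2 and Smoc2 are highest in the Lgr5-enriched libraries, Muc2, Spdef, Atoh1 and Kit in the goblet-enriched libraries, and Krt20, Car1, Slc26a3, Aqp8 and Zg16 in the enterocyte-enriched libraries.

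The goblet-enriched population had far more mucin and secretory transcripts than the Lgr5-enriched population and fewer transcripts of stem cell, Notch and DNA replication genes. The lists behind the lower transcripts were called with the preset correlation and not with an estimated one (adjusted p = 0.535 for stem cell markers, 0.259 for Notch receptors and targets and 0.459 for S phase and DNA replication), and the stem cell call also rested on single libraries. Muc2, the gel-forming mucin of the colon (chromosome 7, 141690340 to 141754693), stood at 11438 ± 1745 TPM (n = 3) against 52.7 ± 14.9 TPM, 217-fold higher. The peptide hormone genes Pyy, Insl5 and Gcg were among the largest falls, while the enteroendocrine list as a whole passed no test (camera adjusted p = 0.574). Pyy stood at 1.03 ± 1.79 against 88.5 ± 36.0 TPM (0 TPM without goblet-enriched replicate 3), Insl5 at 0.956 ± 0.413 against 49.1 ± 20.3 TPM and Gcg at 0.562 ± 0.340 against 33.9 ± 13.2 TPM. In total, 4423 of 12888 genes were called (34.3%), of which 1384 were higher and 3039 lower in the goblet-enriched population.

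All 20 goblet cell markers tested were higher in the goblet-enriched population (20 adjusted over the list alone; median log2 fold change 4.72; camera adjusted p = 1.51e-27, adjusted p = 0.0316 with an estimated correlation). Spink4, a secreted goblet cell peptide, stood at 16662 ± 3924 against 122 ± 12.6 TPM (log2 fold change 7.05, SE 0.28, limma adjusted p = 9.29e-07). Retnlb stood at 2647 ± 2076 against 15.1 ± 10.2 TPM. The 10 deep crypt secretory markers were also all higher (10 adjusted over the list alone; camera adjusted p = 2.36e-15, adjusted p = 0.0316 with an estimated correlation), with Reg4 (chromosome 3, 98222156 to 98236748) at 3297 ± 596 against 75.9 ± 20.3 TPM. Of these, Agr2, Spink4, Muc2 and Tff3 are also in the goblet list. Of the 5 Paneth cell markers tested, 4 were higher (5 adjusted over the list alone; camera adjusted p = 3.83e-05, adjusted p = 0.0492 with an estimated correlation). Ang4 stood at 821 ± 907 against 11.1 ± 7.79 TPM (7.13 TPM without Lgr5-enriched replicate 3) and Mptx2 at 53.4 ± 37.9 against 0.758 ± 0.642 TPM. Without goblet-enriched replicate 3 their means were 302 and 35.05 TPM.

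Among 13 secretory lineage transcription factors, 10 were higher and 1 lower (10 and 1 adjusted over the list alone; camera adjusted p = 3.39e-12, adjusted p = 0.0478 with an estimated correlation). Atoh1 (chromosome 6, 64729125 to 64731245), which specifies secretory cells, stood at 339 ± 25.01 against 5.19 ± 1.59 TPM (log2 fold change 5.81, SE 0.22, limma adjusted p = 5.57e-07). Spdef (chromosome 17, 27714352 to 27728955), which drives goblet maturation, stood at 690 ± 64.6 against 5.97 ± 1.66 TPM, and Gfi1 at 41.6 ± 12.4 against 0.438 ± 0.275 TPM. Sox4 was the lower member, at 22.2 ± 10.7 against 71.6 ± 7.14 TPM. The enzymes of mucin O-glycosylation numbered 16 higher and 2 lower of 22 (16 and 2 adjusted over the list alone; camera adjusted p = 2.41e-12, adjusted p = 0.0478 with an estimated correlation). A4gnt rose to 110 ± 61.5 TPM from 0.595 ± 0.221 TPM, Galnt5 to 127 ± 39.7 TPM from 8.93 ± 1.38 TPM, and B4galnt3 was lower at 17.4 ± 10.9 against 164 ± 55.4 TPM. Of 40 genes of ER folding and secretion, 36 were higher (37 adjusted over the list alone; camera adjusted p = 7.67e-26, adjusted p = 0.118 with an estimated correlation). The disulfide isomerase Pdia5 stood at 552 ± 44.0 against 96.1 ± 2.96 TPM and the stress sensor Ern2 at 448 ± 82.0 against 80.3 ± 22.1 TPM. Cholesterol synthesis had 10 of 20 genes higher and 0 lower (10 adjusted over the list alone; camera adjusted p = 5.01e-06, adjusted p = 0.188 with an estimated correlation). Hmgcs1 stood at 629 ± 88.3 against 273 ± 25.04 TPM.

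The Notch receptors and targets went the other way, with 4 of 4 tested members lower (4 adjusted over the list alone; camera adjusted p = 0.00313, adjusted p = 0.259 with an estimated correlation). Notch1 stood at 8.55 ± 6.30 against 65.5 ± 14.8 TPM and Nrarp, a feedback target of the pathway, at 13.1 ± 6.30 against 57.8 ± 10.9 TPM. Without goblet-enriched replicate 2 the mean of Notch1 was 5.58 TPM. Among 5 Notch ligands, 3 were higher and 1 lower (3 and 2 adjusted over the list alone; camera adjusted p = 0.0308, adjusted p = 0.182 with an estimated correlation). Dll4 stood at 66.6 ± 12.6 against 6.58 ± 2.10 TPM and Dll1 at 64.9 ± 24.05 against 9.98 ± 1.41 TPM, and Jag1 was lower at 9.59 ± 1.35 against 20.9 ± 1.66 TPM. The ligand list lost its call without any single goblet-enriched library (camera adjusted p = 0.207, 0.166 and 0.118 without replicates 1, 2 and 3; range 0.0287 to 0.214). With all libraries kept, it also lost it under median-of-ratios scaling (0.0834) and quantile normalization (0.0619).

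Lgr5 stem cell markers were lower for 9 and higher for 1 of 18 (9 and 2 adjusted over the list alone; camera adjusted p = 0.0384, adjusted p = 0.535 with an estimated correlation). Lgr5 itself (chromosome 10, 115450311 to 115587780) stood at 5.15 ± 3.62 against 37.5 ± 6.37 TPM (log2 fold change -2.89, SE 0.49, limma adjusted p = 0.00242), and Ascl2 (chromosome 7, 142966829 to 142969264), a transcription factor of these stem cells, at 6.82 ± 5.18 against 39.6 ± 10.2 TPM (4.24 TPM without goblet-enriched replicate 2). Tnfrsf19 was the higher member, at 4.80 ± 1.90 against 1.03 ± 0.298 TPM. Of 14 Wnt/beta-catenin targets, 7 were lower and 1 higher (8 and 1 adjusted over the list alone; camera adjusted p = 0.0486, adjusted p = 0.46 with an estimated correlation), and 9 of the 14 are in the stem cell list too. Both calls depended on single libraries: the stem cell list had a camera adjusted p of 0.0513 without Lgr5-enriched replicate 3 and 0.0742 without goblet-enriched replicate 1 (range 0.00545 to 0.0742), and the Wnt list 0.0608, 0.063 and 0.0563 without Lgr5-enriched replicates 1 and 3 and goblet-enriched replicate 1 (range 0.0129 to 0.063).

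Genes of S phase and DNA replication were lower for 27 of 30 (29 adjusted over the list alone; camera adjusted p = 1.48e-06, adjusted p = 0.459 with an estimated correlation). Mcm6, a subunit of the replicative helicase, stood at 63.3 ± 16.2 against 229 ± 54.9 TPM. Of 30 genes of G2/M and mitosis, 19 were lower and 1 higher (24 and 1 adjusted over the list alone; camera adjusted p = 0.000384, adjusted p = 0.535 with an estimated correlation). Under median-of-ratios scaling 7 of these were lower, and without replicate 1 of all populations the camera adjusted p was 0.105 (range 9.44e-07 to 0.105). Mki67, a marker of cycling cells, stood at 119 ± 5.87 against 214 ± 16.8 TPM, whereas Plk1, a mitotic kinase, was higher at 338 ± 41.7 against 130 ± 15.4 TPM. Ribosome biogenesis had 17 of 30 genes lower (23 adjusted over the list alone; camera adjusted p = 8.92e-05, adjusted p = 0.452 with an estimated correlation). Under median-of-ratios scaling 10 of these were lower. Utp20 stood at 21.3 ± 4.86 against 73.2 ± 12.6 TPM. Oxidative phosphorylation had 23 of 37 lower (24 adjusted over the list alone; camera adjusted p = 0.000746, adjusted p = 0.182 with an estimated correlation), and 5 under median-of-ratios scaling. Fatty acid oxidation and ketogenesis had 13 of 24 lower and 1 higher (14 and 1 adjusted over the list alone; camera adjusted p = 0.0103, adjusted p = 0.455 with an estimated correlation), and 6 were lower under median-of-ratios scaling and 7 under quantile normalization. Acsl1 was higher at 77.2 ± 9.27 against 27.5 ± 5.77 TPM.

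Colonocyte, ion transport and enteroendocrine lists did not differ from other genes as a whole but held called members. Colonocyte markers had 5 higher and 5 lower of 27 (5 and 8 adjusted over the list alone; camera adjusted p = 0.465). Guca2a was higher at 804 ± 235 against 121 ± 88.0 TPM (76.1 TPM without Lgr5-enriched replicate 2). Ion and water transport had 4 higher and 10 lower of 27 (4 and 11 adjusted over the list alone; camera adjusted p = 0.239, adjusted p = 0.59 with an estimated correlation). Best2 stood at 94.4 ± 64.0 against 2.70 ± 1.65 TPM (59.2 TPM without goblet-enriched replicate 2) and Kcnq1, a potassium channel, at 21.5 ± 17.4 against 218 ± 73.1 TPM. The list was called under median-of-ratios scaling (camera adjusted p = 0.0424, and 0.425 with an estimated correlation), quantile normalization (0.0267 and 0.354) and without goblet-enriched replicate 3 (0.0263; range 0.0101 to 0.426). That library carried more colonocyte transcripts than the other goblet-enriched libraries: the mean log2(TPM + 1) over the colonocyte markers was 5.64 there and 4.22 and 4.62 in replicates 1 and 2. Car1 (20.2 ± 25.5 against 99.0 ± 100 TPM) and Slc26a3 (7.41 ± 10.9 against 14.7 ± 2.49 TPM) were not called, and both were called lower without goblet-enriched replicate 3 (limma adjusted p = 0.00942 and 0.00175). Car1 was also called without Lgr5-enriched replicate 3 (0.0491) and Slc26a3 with array weights (0.0277). Their goblet-enriched means were 5.51 and 1.11 TPM without replicate 3, and the Lgr5-enriched mean of Car1 41.6 TPM without replicate 1. The ranges were 0.00942 to 0.32 for Car1 and 0.00175 to 0.439 for Slc26a3. Enteroendocrine markers had 3 higher and 5 lower of 17 (3 and 6 adjusted over the list alone; camera adjusted p = 0.574), where Pcsk1, a prohormone convertase, was higher at 26.3 ± 4.88 against 4.31 ± 0.749 TPM. Tuft cell markers had 2 of 8 higher (2 adjusted over the list alone; camera adjusted p = 0.0403, adjusted p = 0.535 with an estimated correlation), Rgs13 and Avil. Goblet-enriched replicate 3 stood apart here as well, with a mean log2(TPM + 1) of 3.28 against at most 2.12 in any other library, and without it the camera adjusted p was 0.233. It was 0.0606 and 0.0619 without Lgr5-enriched replicates 1 and 2 (range 0.00211 to 0.234). The tuft list also lost its call with all libraries kept, under median-of-ratios scaling (0.13), quantile normalization (0.0709) and limma-voom (0.0773).

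BMP response genes had 1 higher and 4 lower of 10 (1 and 5 adjusted over the list alone; camera adjusted p = 0.407). Id1 stood at 31.6 ± 19.7 against 177 ± 24.04 TPM and Id4 at 23.0 ± 19.9 against 0.498 ± 0.371 TPM (11.6 TPM without goblet-enriched replicate 1). Under median-of-ratios scaling 2 of the 10 were lower. Antimicrobial and barrier genes had 5 higher and 4 lower of 22 (5 and 5 adjusted over the list alone; camera adjusted p = 0.358). Nlrp6 stood at 19.6 ± 12.2 against 180 ± 21.4 TPM. Brush border genes had 3 of 18 lower (2 adjusted over the list alone; camera adjusted p = 0.604). Mall stood at 3.88 ± 4.62 against 33.6 ± 3.68 TPM (1.29 TPM without goblet-enriched replicate 3, which carried colonocyte transcripts). Under median-of-ratios scaling 1 of the 18 was lower. Interferon-stimulated genes had 2 of 27 higher (2 adjusted over the list alone; camera adjusted p = 0.0703, 0.742 with an estimated correlation, and 0.00826, 0.049 and 0.00176 without Lgr5-enriched replicates 1 and 3 and goblet-enriched replicate 2; range 0.00176 to 0.571). Rsad2 stood at 19.3 ± 4.84 against 5.48 ± 1.93 TPM. Genes of dissociation and the immediate early response had 2 higher and 1 lower of 20 (0 and 0 adjusted over the list alone, and 0 and 0 under quantile normalization; camera adjusted p = 0.194). The 3 leukocyte and 3 stromal genes tested were too few for a list test: of the former 0 were called (limma; 0 at an unadjusted p under 0.05, 0 by limma-voom on the recovered reads and 0 with a replicate block), and of the latter Tagln was higher at 34.1 ± 2.19 against 10.97 ± 1.93 TPM and Vim lower at 2.19 ± 1.99 against 6.16 ± 0.980 TPM (1.12 TPM without goblet-enriched replicate 3; limma adjusted p = 0.0378, range 0.00424 to 0.19). The call of Vim ended without Lgr5-enriched replicate 1, 2 or 3 (0.056, 0.087 and 0.111), goblet-enriched replicate 1 or 2 (0.0787 and 0.0809) or enterocyte-enriched replicate 2 (0.0516). It also ended under median-of-ratios scaling (0.0783), quantile normalization (0.0588), a pseudocount of 0.1 (0.0551), no filter on low values (0.0661) and the fit to the 6 libraries compared (0.061). Of 7 genes for MHC class II presentation, limma called 0 without a block (0 at an unadjusted p under 0.05 and 0 by limma-voom; camera adjusted p = 0.67). Their level differed most between replicate numbers, with mean log2(TPM + 1) of 8.43, 6.57 and 8.44 in replicate 1 of the Lgr5-enriched, goblet-enriched and enterocyte-enriched populations and 3.20 to 5.67 in the other 6 libraries. With a replicate block 6 of the 7 were called, and Cd74 and H2-Aa were lower in the goblet-enriched population (log2 fold change -1.90 and -2.29, limma adjusted p = 0.00163 and 0.00322), as they were with array weights (0.0342 and 0.0472).

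The split of calls moved with the scaling. The median log2 fold change of all tested genes was -0.26 as deposited and -0.05 under median-of-ratios scaling, where 3388 genes were called, 1839 higher and 1549 lower. No overlap between the 3 and 3 libraries was seen for 6182 genes (48.0%, against 10% by chance). Without Lgr5-enriched replicate 3, 2646 genes were called, and without replicate 1 of all populations 5592.

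Compared with the Lgr5-enriched population, the enterocyte-enriched population had higher transcripts of surface colonocyte genes, goblet cell products and mitochondrial respiration, and lower transcripts of stem cell, Wnt target, cell cycle and ribosome biogenesis genes. Of these lists, goblet cell markers and oxidative phosphorylation were also called with an estimated correlation, and the others were not (adjusted p = 0.0956 for colonocyte markers, 0.296 for stem cell markers, 0.18 for Wnt targets, 0.396 and 0.347 for S phase and G2/M, and 0.26 for ribosome biogenesis). Car4, a membrane carbonic anhydrase of surface colonocytes (chromosome 11, 84957786 to 84966044), stood at 961 ± 900 TPM (n = 3) against 8.64 ± 3.69 TPM, 111-fold higher. Without the library labelled enterocyte-enriched replicate 1 the mean was 446 TPM, 51.6-fold higher. Lgr5 stood at 0.126 ± 0.181 against 37.5 ± 6.37 TPM (log2 fold change -5.09, SE 0.49, limma adjusted p = 0.000187). In total 6396 of 12888 genes were called (49.6%), 1549 higher and 4847 lower.

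Of 27 colonocyte markers, 25 were higher and 0 lower (25 adjusted over the list alone; median log2 fold change 3.26; camera adjusted p = 1.08e-18, adjusted p = 0.0956 with an estimated correlation). Krt20 (chromosome 11, 99428403 to 99438150), a keratin of differentiated surface cells, stood at 879 ± 627 against 13.5 ± 5.28 TPM (log2 fold change 5.76, SE 0.84, limma adjusted p = 0.000701), and the water channel Aqp8 (chromosome 7, 123462291 to 123468004) at 322 ± 258 against 4.04 ± 1.54 TPM. The means were 522 and 172.7 TPM without the library labelled enterocyte-enriched replicate 1. Ion and water transport had 16 higher and 6 lower of 27 (16 and 6 adjusted over the list alone; camera adjusted p = 3.09e-05, adjusted p = 0.164 with an estimated correlation). The sodium-proton exchanger Slc9a3 stood at 68.0 ± 34.3 against 0.944 ± 0.436 TPM, the chloride-bicarbonate exchanger Slc26a3 (chromosome 12, 31390871 to 31473917) at 532 ± 290 against 14.7 ± 2.49 TPM, and Aqp1 was lower at 11.1 ± 7.64 against 174 ± 64.8 TPM (7.11 TPM without enterocyte-enriched replicate 3). Brush border genes were higher for 12 and lower for 1 of 18 (12 and 1 adjusted over the list alone; camera adjusted p = 9.42e-08, adjusted p = 0.164 with an estimated correlation). Cdhr5, a cadherin linking microvilli, stood at 832 ± 212 against 151 ± 58.8 TPM. Among the largest rises was that of Saa1, an acute-phase apolipoprotein (chromosome 7, 46740497 to 46742980), at 1895 ± 2155 against 11.6 ± 6.26 TPM (log2 fold change 6.75, SE 1.18, limma adjusted p = 0.0016), and that of Tgm3, a transglutaminase, at 822 ± 139 against 10.8 ± 7.03 TPM (log2 fold change 6.38). Without the library labelled enterocyte-enriched replicate 1 the mean of Saa1 was 653 TPM and its log2 fold change 5.83, below that of Tgm3 (6.26).

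Goblet cell markers were higher for 17 of 20 (17 adjusted over the list alone; median log2 fold change 3.63; camera adjusted p = 1.16e-16, adjusted p = 0.0492 with an estimated correlation). Zg16, a lectin-like goblet cell product (chromosome 7, 127050156 to 127087328), stood at 5481 ± 2152 against 95.2 ± 34.2 TPM, Clca1 at 2756 ± 865 against 54.4 ± 32.0 TPM, Fcgbp at 1454 ± 625 against 28.2 ± 11.9 TPM and Muc2 at 1207 ± 201 against 52.7 ± 14.9 TPM. The deep crypt secretory markers had 8 higher and 1 lower of 10 (9 and 1 adjusted over the list alone; camera adjusted p = 2.36e-07, adjusted p = 0.0732 with an estimated correlation). Tff3 stood at 1918 ± 677 against 48.1 ± 8.65 TPM and Cd24a was lower at 278 ± 94.2 against 806 ± 148 TPM. Paneth cell markers had 4 of 5 higher (4 adjusted over the list alone; camera adjusted p = 0.000932, adjusted p = 0.0956 with an estimated correlation). Secretory transcription factors had 5 higher and 2 lower of 13 (7 and 2 adjusted over the list alone; camera adjusted p = 0.00144, adjusted p = 0.224 with an estimated correlation), and 8 higher and 1 lower under median-of-ratios scaling. Atoh1 stood at 64.9 ± 13.9 against 5.19 ± 1.59 TPM and Spdef at 58.4 ± 10.6 against 5.97 ± 1.66 TPM. Mucin O-glycosylation had 11 higher and 2 lower of 22 (11 and 2 adjusted over the list alone; camera adjusted p = 1.62e-05, adjusted p = 0.126 with an estimated correlation). The sialyltransferase St3gal4 stood at 535 ± 220 against 50.3 ± 20.2 TPM.

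Oxidative phosphorylation was higher for 19 and lower for 1 of 37 (20 and 1 adjusted over the list alone; median log2 fold change 0.38; camera adjusted p = 8.05e-12, adjusted p = 0.0478 with an estimated correlation), and under median-of-ratios scaling for 35 and 0. Cox6c, a subunit of cytochrome c oxidase, stood at 1325 ± 74.8 against 772 ± 27.4 TPM. Fatty acid oxidation and ketogenesis had 8 higher and 1 lower of 24 (8 and 1 adjusted over the list alone; camera adjusted p = 2.23e-05, adjusted p = 0.248 with an estimated correlation), 18 and 0 under median-of-ratios scaling. The carnitine carrier Slc25a20 stood at 179 ± 78.3 against 26.1 ± 5.54 TPM. Cholesterol synthesis had 5 of 20 higher (2 adjusted over the list alone; camera adjusted p = 0.0007, adjusted p = 0.296 with an estimated correlation), 13 under median-of-ratios scaling. Msmo1 stood at 344 ± 31.9 against 173 ± 9.67 TPM. ER folding had 2 higher and 5 lower of 40 (0 and 0 adjusted over the list alone; median -0.14; camera adjusted p = 0.174, adjusted p = 0.749 with an estimated correlation) and its median changed sign under median-of-ratios scaling, where 12 were higher and 0 lower with a median of 0.27. As a list it was called with the preset correlation under that scaling (0.0291; 0.652 with an estimated one) and without Lgr5-enriched replicate 1 (0.00986) or the library labelled enterocyte-enriched replicate 2 (0.0393; range 0.00986 to 0.987).

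All 30 genes of S phase and DNA replication and all 30 of G2/M and mitosis were lower (30 in each adjusted over the list alone; camera adjusted p = 2.32e-09 and 4.28e-10, adjusted p = 0.396 and 0.347 with an estimated correlation). Mki67 (chromosome 7, 135689784 to 135716361) stood at 39.95 ± 11.4 against 214 ± 16.8 TPM and Mcm6 at 31.01 ± 18.3 against 229 ± 54.9 TPM (20.4 TPM without enterocyte-enriched replicate 3). Ribosome biogenesis had 29 of 30 lower (29 adjusted over the list alone; camera adjusted p = 2.92e-09, adjusted p = 0.26 with an estimated correlation). Nop56 stood at 35.6 ± 11.6 against 148 ± 15.3 TPM. Lgr5 stem cell markers had 15 lower and 1 higher of 18 (15 and 1 adjusted over the list alone; camera adjusted p = 6.87e-05, adjusted p = 0.296 with an estimated correlation), and 14 of 14 Wnt/beta-catenin targets were lower (14 adjusted over the list alone; camera adjusted p = 1.34e-05, adjusted p = 0.18 with an estimated correlation). Smoc2, a stem cell marker (chromosome 17, 14279506 to 14404790), stood at 3.22 ± 2.29 against 184 ± 29.1 TPM (1.91 TPM without enterocyte-enriched replicate 3) and Ascl2 at 0.372 ± 0.378 against 39.6 ± 10.2 TPM, whereas the water channel Aqp4 was higher at 572 ± 40.1 against 254 ± 58.8 TPM. The 4 Notch receptors and targets were lower (4 adjusted over the list alone; camera adjusted p = 0.0347, adjusted p = 0.424 with an estimated correlation). Hes1, the main transcriptional target, stood at 80.5 ± 12.9 against 273 ± 6.90 TPM. Notch ligands had 2 higher and 1 lower of 5 (2 and 1 adjusted over the list alone; camera adjusted p = 0.262).

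Interferon-stimulated genes were higher for 11 of 27 (11 adjusted over the list alone; camera adjusted p = 4.41e-07, adjusted p = 0.424 with an estimated correlation). Ifit1 stood at 22.1 ± 15.3 against 0.995 ± 0.667 TPM. The library labelled enterocyte-enriched replicate 1 had the highest mean over this list, 5.69 on the log2(TPM + 1) scale. Of the 3 leukocyte genes tested, 2 were higher, Lyz2 at 126 ± 110 against 7.25 ± 6.54 TPM and Tyrobp at 6.33 ± 5.75 against 0.105 ± 0.181 TPM. Leukocyte transcripts stood highest in the libraries labelled enterocyte-enriched replicates 1 and 2 (means of 4.15 and 3.65 on the same scale, against at most 1.85 in the others). The 2 calls ended under several alternatives. With all libraries kept, that of Lyz2 ended with a pseudocount of 0.1 (limma adjusted p = 0.0735), with no filter on low values (0.0671) and by limma-voom (0.061), and that of Tyrobp with no filter (0.0521) and in the fit to the 6 libraries compared (0.0528). Without the library labelled enterocyte-enriched replicate 1, or replicate 2, the limma adjusted p was 0.13 and 0.103 for Lyz2 and 0.109 and 0.0947 for Tyrobp, and without the former the means were 72.9 and 3.61 TPM. The Lgr5-enriched mean of Lyz2 was 4.53 TPM without replicate 2. Without Lgr5-enriched replicate 1 or 3 it was 0.123 and 0.055 for Lyz2 and 0.0715 and 0.0604 for Tyrobp, and without Lgr5-enriched replicate 2 it was 0.0735 for Tyrobp (ranges 0.0135 to 0.151 and 0.000876 to 0.162). Of the 3 stromal genes, Tagln was higher at 18.2 ± 2.38 against 10.97 ± 1.93 TPM. Tuft cell markers had 1 of 8 lower, Hpgds (1 adjusted over the list alone; camera adjusted p = 0.138). Enteroendocrine markers had 2 higher and 1 lower of 17 (0 and 0 adjusted over the list alone; camera adjusted p = 0.0303, adjusted p = 0.475 with an estimated correlation), 4 and 1 under median-of-ratios scaling and quantile normalization. Insl5 was lower at 18.4 ± 7.96 against 49.1 ± 20.3 TPM, and the list lost its call under median-of-ratios scaling (0.249), quantile normalization (0.06) and limma-voom (0.0663), without the library labelled enterocyte-enriched replicate 1 (0.0745), enterocyte-enriched replicate 3 (0.0807) or Lgr5-enriched replicate 2 (0.0612; range 0.0135 to 0.249). BMP response had 4 higher and 3 lower of 10 (4 and 3 adjusted over the list alone; camera adjusted p = 0.0403, adjusted p = 0.23 with an estimated correlation). Bmp2 stood at 51.6 ± 25.3 against 15.2 ± 3.64 TPM. It too lost its call under median-of-ratios scaling (0.195), quantile normalization (0.128) and limma-voom (0.0542), without the library labelled enterocyte-enriched replicate 1 (0.0907) and without Lgr5-enriched replicate 3 (0.0726; range 0.0196 to 0.195). For Chga, a granin of enteroendocrine cells, the levels were 39.2 ± 8.90 against 18.6 ± 11.9 TPM, not called without a block (limma adjusted p = 0.202) and called with a replicate block (0.0267; range 0.0131 to 0.552).

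Antimicrobial and barrier genes had 7 higher and 2 lower of 22 (7 and 2 adjusted over the list alone). Their median log2 fold change was -0.09 and their mean 0.55, and the camera test gave a rise (adjusted p = 0.00658, adjusted p = 0.44 with an estimated correlation) that was lost under median-of-ratios scaling (0.132, with a median of 0.33) and quantile normalization (0.168; range 0.000632 to 0.168). Nox1, an epithelial oxidase, was lower at 15.95 ± 11.8 against 411 ± 314 TPM. The means were 10.09 TPM without the library labelled enterocyte-enriched replicate 1 and 235 TPM without Lgr5-enriched replicate 1. MHC class II genes, which varied with the replicate number as described, had 0 of 7 called by limma (0 at an unadjusted p under 0.05 and 0 by limma-voom; camera adjusted p = 0.601). With a replicate block 3 were called, among them Cd74 as lower (log2 fold change -0.91, limma adjusted p = 0.026). Dissociation and immediate early genes had 4 of 20 lower (4 adjusted over the list alone; camera adjusted p = 0.608; median -0.19, and 0.23 under median-of-ratios scaling, where 2 were higher and 1 lower). The heat shock gene Hsph1 stood at 55.0 ± 4.21 against 249 ± 151 TPM (162 TPM without Lgr5-enriched replicate 1).

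Among all genes the median log2 fold change was -0.35 as deposited and 0.02 under median-of-ratios scaling, where 5567 genes were called, 3033 higher and 2534 lower, so the balance of directions among all calls followed the scaling. The libraries did not overlap for 7976 genes (61.9%, against 10% by chance). Without the library labelled enterocyte-enriched replicate 1, 5225 genes were called, and without replicate 1 of all populations 6919.

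**Figure D4:**
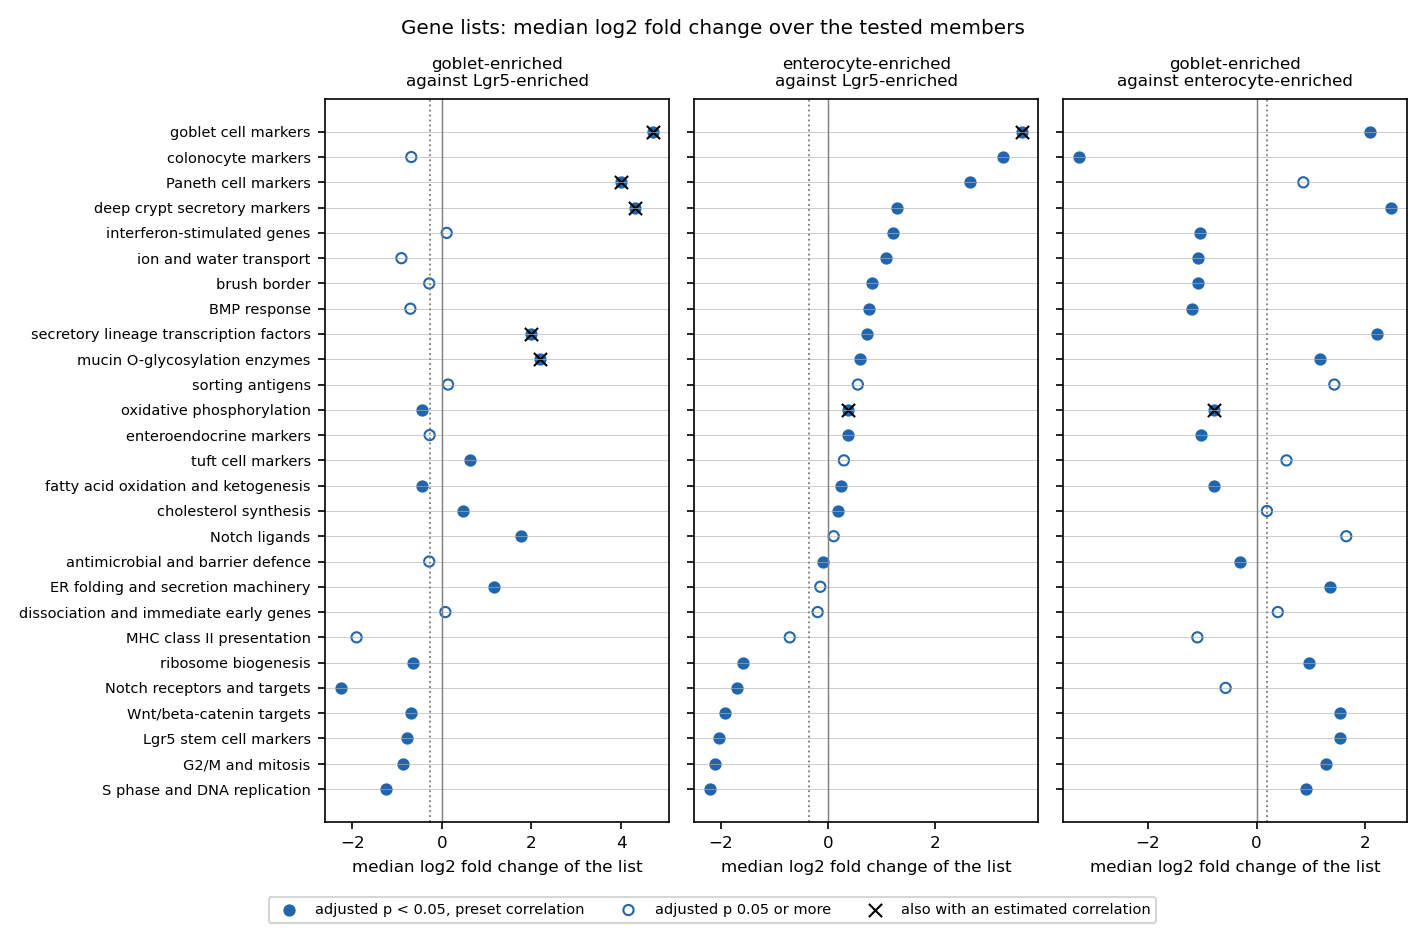
Median log2 fold change of the tested members of 27 gene lists in the 3 comparisons, with 1 point per list. Filled points have a camera adjusted p below 0.05 with the preset correlation, a cross marks those also called with an estimated correlation (8 of the 57 called), and the dotted line is the median of all tested genes (-0.26, -0.35 and 0.20).

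Between the crypt-bottom goblet-enriched and the crypt-top enterocyte-enriched populations, the goblet-enriched cells had higher transcripts of secretory transcription factors, the ER, glycosylation and the cell cycle, and lower transcripts of colonocyte, brush border, ion transport and mitochondrial genes. Of these lists, oxidative phosphorylation was also called with an estimated correlation (adjusted p = 0.0316), and the others were not (0.126 to 0.543). Carbonic anhydrase Car1 (chromosome 3, 14766216 to 14808368) stood at 20.2 ± 25.5 TPM (n = 3) in the goblet-enriched population and 1319 ± 326 TPM in the enterocyte-enriched population, 65.3-fold lower. Without goblet-enriched replicate 3, which carried more colonocyte transcripts than the other goblet-enriched libraries, the mean was 5.51 TPM, 239-fold lower. Etv5, an ETS transcription factor, stood at 153 ± 18.4 against 4.40 ± 2.06 TPM (log2 fold change 4.89, SE 0.30, limma adjusted p = 2.37e-05). In total 5687 of 12888 genes were called (44.1%), 3633 higher and 2054 lower in the goblet-enriched population.

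Goblet cell markers were higher for 12 and lower for 2 of 20 (12 and 2 adjusted over the list alone; median log2 fold change 2.09; camera adjusted p = 0.000493, adjusted p = 0.259 with an estimated correlation). Muc2 stood at 11438 ± 1745 against 1207 ± 201 TPM and Agr2, a disulfide isomerase needed for mucin folding, at 21551 ± 7105 against 2770 ± 459 TPM (log2 fold change 2.92, SE 0.25, limma adjusted p = 5.83e-05). Zg16 was 15.9-fold lower, at 345 ± 223 against 5481 ± 2152 TPM (log2 fold change -4.17, SE 0.53, limma adjusted p = 0.000331). Deep crypt secretory markers had 9 higher and 1 lower of 10 (9 and 1 adjusted over the list alone; camera adjusted p = 0.000253, adjusted p = 0.153 with an estimated correlation). The lower member was Tff3, at 1120.3 ± 89.0 against 1918 ± 677 TPM (limma adjusted p = 0.0315), a call lost without the library labelled enterocyte-enriched replicate 1 (0.0658) and without goblet-enriched replicate 1, 2 or 3 (0.056, 0.0623 and 0.0921; range 0.00907 to 0.111). With all libraries kept the call of Tff3 ended under quantile normalization (0.111), with no filter on low values (0.052) and in the fit to the 6 libraries compared (0.0574). Of 13 secretory transcription factors 11 were higher (12 adjusted over the list alone; camera adjusted p = 7.9e-06, adjusted p = 0.126 with an estimated correlation). Spdef stood at 690 ± 64.6 against 58.4 ± 10.6 TPM and Bhlha15, a factor of professional secretory cells, at 31.4 ± 7.45 against 3.17 ± 0.774 TPM. ER folding and secretion had 38 of 40 higher (38 adjusted over the list alone; camera adjusted p = 2.98e-12, adjusted p = 0.224 with an estimated correlation). The retrieval receptor Kdelr3 stood at 203 ± 38.4 against 21.7 ± 7.55 TPM. Mucin O-glycosylation had 16 higher and 5 lower of 22 (16 and 5 adjusted over the list alone; camera adjusted p = 0.00364, adjusted p = 0.228 with an estimated correlation). B3gnt6 stood at 74.8 ± 45.3 against 1.49 ± 0.689 TPM.

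Cell cycle genes were higher in the goblet-enriched population, 29 of 30 for G2/M and mitosis (30 adjusted over the list alone; camera adjusted p = 1.73e-07, adjusted p = 0.433 with an estimated correlation) and 17 of 30 for S phase and DNA replication (20 adjusted over the list alone; camera adjusted p = 0.000313, adjusted p = 0.543 with an estimated correlation). Plk1 stood at 338 ± 41.7 against 84.3 ± 16.7 TPM and Fen1, a replication nuclease, at 36.3 ± 5.76 against 14.2 ± 3.55 TPM. Ribosome biogenesis had 24 higher and 1 lower of 30 (26 and 1 adjusted over the list alone; camera adjusted p = 3.09e-05, adjusted p = 0.435 with an estimated correlation). Gnl3 stood at 116 ± 16.5 against 30.5 ± 12.9 TPM. Lgr5 stem cell markers had 15 higher and 1 lower of 18 (15 and 1 adjusted over the list alone; camera adjusted p = 0.000457, adjusted p = 0.373 with an estimated correlation) and Wnt/beta-catenin targets 11 of 14 higher (11 adjusted over the list alone; camera adjusted p = 0.000407, adjusted p = 0.241 with an estimated correlation). The ephrin receptor Ephb3 stood at 76.2 ± 19.4 against 10.6 ± 6.01 TPM and Smoc2 at 54.1 ± 9.13 against 3.22 ± 2.29 TPM (1.91 TPM without enterocyte-enriched replicate 3). Notch ligands had 3 higher and 1 lower of 5 (3 and 1 adjusted over the list alone; camera adjusted p = 0.288). Dll4 stood at 66.6 ± 12.6 against 14.4 ± 3.35 TPM, and 0 of the 4 Notch receptors and targets were called by limma (1 at an unadjusted p under 0.05, 1 by limma-voom and 1 with a replicate block; camera adjusted p = 0.262). Hes1 stood at 88.5 ± 17.5 against 80.5 ± 12.9 TPM.

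Of 27 colonocyte markers, 23 were lower and 1 higher (23 and 1 adjusted over the list alone; camera adjusted p = 4.05e-13, adjusted p = 0.136 with an estimated correlation). Slc26a3 stood at 7.41 ± 10.9 against 532 ± 290 TPM (1.11 TPM without goblet-enriched replicate 3), and the higher member was the peptide Guca2b at 160 ± 36.7 against 34.3 ± 8.80 TPM. Ion and water transport had 16 lower and 4 higher of 27 (19 and 4 adjusted over the list alone; camera adjusted p = 8.78e-07, adjusted p = 0.126 with an estimated correlation), and brush border 13 lower and 1 higher of 18 (15 and 1 adjusted over the list alone; camera adjusted p = 7.04e-08, adjusted p = 0.164 with an estimated correlation). Cdhr2 stood at 60.6 ± 11.8 against 361 ± 65.2 TPM. Oxidative phosphorylation was lower for 36 and higher for 1 of 37 (36 and 1 adjusted over the list alone; median log2 fold change -0.78; camera adjusted p = 4.74e-17, adjusted p = 0.0316 with an estimated correlation). Cox5a stood at 558 ± 36.6 against 1370.4 ± 35.4 TPM (log2 fold change -1.30, SE 0.12, limma adjusted p = 7.01e-05), and the higher member was Ndufa4 at 700 ± 57.1 against 439 ± 42.0 TPM. Fatty acid oxidation and ketogenesis had 19 lower and 1 higher of 24 (19 and 1 adjusted over the list alone; camera adjusted p = 2.32e-09, adjusted p = 0.153 with an estimated correlation). Slc16a1, a carrier of lactate and short-chain acids, stood at 44.0 ± 6.17 against 273 ± 19.6 TPM. Cholesterol synthesis had 6 higher and 2 lower of 20 (6 and 2 adjusted over the list alone; camera adjusted p = 0.465). Lss stood at 64.7 ± 4.05 against 34.4 ± 10.3 TPM.

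Interferon-stimulated genes were lower in the goblet-enriched population for 10 of 27 (7 adjusted over the list alone; camera adjusted p = 0.000213, adjusted p = 0.507 with an estimated correlation). Ifit1 stood at 1.36 ± 1.17 against 22.1 ± 15.3 TPM (0.711 TPM without goblet-enriched replicate 3). Enteroendocrine markers had 6 lower and 3 higher of 17 (6 and 3 adjusted over the list alone; camera adjusted p = 0.0221, adjusted p = 0.46 with an estimated correlation). Pyy stood at 1.03 ± 1.79 against 41.7 ± 18.5 TPM (0 TPM without goblet-enriched replicate 3) and Pcsk1 was higher at 26.3 ± 4.88 against 2.98 ± 0.329 TPM. Chga, at 13.4 ± 11.2 against 39.2 ± 8.90 TPM, was called with a replicate block (limma adjusted p = 0.00571; 0.0769 without) and with array weights (0.0251), and also without Lgr5-enriched replicate 1 (0.0457) or goblet-enriched replicate 3 (0.0369, with a mean of 7.98 TPM; range 0.00525 to 0.224). BMP response had 6 lower and 2 higher of 10 (6 and 2 adjusted over the list alone; camera adjusted p = 0.0372, adjusted p = 0.228 with an estimated correlation). Id3 stood at 25.6 ± 7.49 against 288 ± 100 TPM. Without the library labelled enterocyte-enriched replicate 1 the camera adjusted p was 0.0795 for the enteroendocrine and 0.0746 for the BMP list, and under median-of-ratios scaling 0.0881 and 0.0934 (ranges 0.00367 to 0.17 and 0.0157 to 0.0934). The enteroendocrine list was at 0.0542 by limma-voom and the BMP list at 0.06 under quantile normalization. Without goblet-enriched replicate 1 it was 0.0915 for the enteroendocrine list. Antimicrobial and barrier genes had 6 lower and 2 higher of 22 (6 and 2 adjusted over the list alone; camera adjusted p = 0.0465, adjusted p = 0.535 with an estimated correlation). That call was lost with a replicate block (0.086), under median-of-ratios scaling (0.177), quantile normalization (0.168) and limma-voom (0.0763), without the library labelled enterocyte-enriched replicate 1 (0.199), without goblet-enriched replicate 2 (0.154) and without Lgr5-enriched replicate 2 or 3 (0.0516 and 0.05; range 0.00861 to 0.199). Lypd8 stood at 1050 ± 398 against 20073 ± 11596 TPM, the cytokine Il18 at 23.7 ± 11.5 against 466 ± 15.5 TPM, and Muc4 was higher at 472 ± 111 against 40.2 ± 12.3 TPM.

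Paneth cell markers had 2 of 5 higher (2 adjusted over the list alone, 0 under quantile normalization; camera adjusted p = 0.465), tuft cell markers 2 of 8 (2 adjusted over the list alone; camera adjusted p = 0.737), and dissociation and immediate early genes 1 higher and 1 lower of 20 (1 and 1 adjusted over the list alone; camera adjusted p = 0.617). MHC class II genes had 0 of 7 called by limma (0 at an unadjusted p under 0.05 and 0 by limma-voom; camera adjusted p = 0.262, adjusted p = 0.742 with an estimated correlation). With a replicate block 4 were called and the list was called lower with the preset correlation (camera adjusted p = 0.0198; range 0.0198 to 0.963) and not with an estimated one (0.478). Among the 4 genes called with the block, Cd74 and H2-Aa were lower (log2 fold change -0.99 and -1.76, limma adjusted p = 0.0203 and 0.00787). Of the 3 stromal genes Tagln was higher at 34.1 ± 2.19 against 18.2 ± 2.38 TPM, and of the 3 leukocyte genes Lyz2 was lower (limma adjusted p = 0.0434; 0 adjusted over the list alone), a call that ended without the library labelled enterocyte-enriched replicate 1, or replicate 2 (0.142 and 0.114), goblet-enriched replicate 1 or 3 (0.139 and 0.0608) or Lgr5-enriched replicate 3 (0.0555; range 0.0158 to 0.145). It also ended with a pseudocount of 0.1 (0.101), no filter on low values (0.0743), array weights (0.0689) and limma-voom (0.122).

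The median log2 fold change of all genes was 0.20 as deposited and 0.04 under median-of-ratios scaling, where 5304 genes were called, 2553 higher and 2751 lower. The libraries did not overlap for 7276 genes (56.5%, against 10% by chance). Without the library labelled enterocyte-enriched replicate 1, 4493 genes were called, and without replicate 1 of all populations 5943.

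Each population had genes called and at least 2-fold higher than in both others. The Lgr5-enriched population had 499, including Lgr5, the oxidase Nox1 at 411 ± 314 against 38.6 ± 16.8 and 15.95 ± 11.8 TPM in the goblet-enriched and enterocyte-enriched populations, the iron carrier Trf at 180 ± 152 against 16.9 ± 4.05 and 7.63 ± 2.97 TPM, the fucosyltransferase Fut9 at 30.2 ± 2.84 against 3.32 ± 1.83 and 2.12 ± 1.26 TPM, and Cnn3, Kif12, Rgs10 and Cttnbp2. The means of Nox1 and Trf were 235 and 92.98 TPM without Lgr5-enriched replicate 1. The goblet-enriched population had 576, including the long non-coding RNAs Rian (68.1 ± 22.5 TPM, against 0.116 ± 0.0783 in the Lgr5-enriched and 0.881 ± 0.135 in the enterocyte-enriched population) and Meg3, the matricellular gene Nov at 788 ± 387 against 4.16 ± 1.95 and 68.4 ± 53.7 TPM, the chemokine Ccl9 at 82.8 ± 45.9 against 1.58 ± 1.09 (0.947 TPM without Lgr5-enriched replicate 1) and 1.88 ± 0.504 TPM, the metallothionein Mt3, the collagen Col8a1, B3gnt6, and the small RNA gene AF357359, which was listed at 0 in all 3 Lgr5-enriched libraries. The enterocyte-enriched population had 511, including Saa1, Tgm3, Car4, Krt20, Aqp8, the sugar phosphate exchanger Slc37a2 at 153 ± 91.4 against 1.52 ± 0.668 and 1.94 ± 3.08 TPM in the Lgr5-enriched and goblet-enriched populations, the adhesion gene Ceacam20 at 167 ± 95.3 against 2.38 ± 0.228 and 2.33 ± 3.54 TPM, and the protease Prss30 at 295 ± 246 against 4.76 ± 1.59 and 4.33 ± 6.52 TPM. The means of Slc37a2 and Prss30 were 100.3 and 152.5 TPM without the library labelled enterocyte-enriched replicate 1. The goblet-enriched means of Slc37a2, Ceacam20 and Prss30 were 0.168, 0.292 and 0.566 TPM without replicate 3.

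These counts are overlaps of pairs of comparisons that share the libraries of a population. Independent lists of the observed sizes would share 186.6, 98.6 and 68.0 genes. Part of the excess may come from the shared libraries, which were too few to split. Without Lgr5-enriched replicate 3 the Lgr5-enriched count was 326, under median-of-ratios scaling it was 224 and the enterocyte-enriched count 825, without the library labelled enterocyte-enriched replicate 1 the latter was 388, and without replicate 1 of all populations the counts were 372, 518 and 355.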

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

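The alternatives chosen after seeing the data are named with the methods. No named gene or list result that was called, as reported or under an alternative, reversed the direction of its test (for lists, relative to all other genes). The median of the ER folding list for enterocyte-enriched against Lgr5-enriched changed sign under median-of-ratios scaling (-0.14 and 0.27), while its camera direction against other genes was up in both. Of 310 named gene results, 289 were called and 209 had the same call under every alternative. A call was lost in at least 1 setting for 87, and for 41 of these with at most 1 library left out. Of 81 list results, 66 had the same call under every alternative with the preset correlation, and with an estimated correlation 8 of the 57 calls held.

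The replicate block gave 6357, 7891 and 7336 genes for goblet-enriched against Lgr5-enriched, enterocyte-enriched against Lgr5-enriched and goblet-enriched against enterocyte-enriched, and 9761 among the 3 populations. It added calls for Cd74, H2-Aa and Chga and the MHC class II list and ended that of the antimicrobial list, all given in the report. It changed no other call of a named gene or list.

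With all libraries kept, counts of genes stayed within 1.5 times the reported ones except as follows, and the cause was not tested unless stated. Array weights gave 7611 genes for goblet-enriched against Lgr5-enriched. Genes highest in the Lgr5-enriched population numbered 247 with a pseudocount of 5, 224 under median-of-ratios scaling, 263 with a replicate block added to it, and 260 under quantile normalization. Genes highest in the enterocyte-enriched population numbered 825 under median-of-ratios scaling and 886 with a replicate block added. Asking for at least 4-fold left 35, 158 and 182 genes highest in the Lgr5-enriched, goblet-enriched and enterocyte-enriched populations, by its construction.

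With single libraries or all libraries of a replicate number left out, the counts ranged from 1069 to 5592 for goblet-enriched against Lgr5-enriched, 3351 to 6919 for enterocyte-enriched against Lgr5-enriched, 2696 to 5943 for goblet-enriched against enterocyte-enriched and 3998 to 8645 among the 3 populations. The ranges for genes highest in the Lgr5-enriched and goblet-enriched populations were 204 to 546 and 351 to 570. Without all of replicate 2 the counts were 1399, 3556, 2696 and 4377 in the order given, and 289 genes were highest in the Lgr5-enriched population. Without all of replicate 3 they were 1069, 3351, 2791 and 3998. In these fits 6 libraries remained, as in the one without replicate 1, which gave the highest of the first 4 counts, so the number of libraries alone does not account for the low counts. Their cause was not tested. Of single libraries, only Lgr5-enriched replicate 3 moved a count by over 1.5 times (2646 genes for goblet-enriched against Lgr5-enriched, 326 highest in the Lgr5-enriched population).

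Rescaling to TPM was not run because the values are TPM already, and merging of shared symbols because no symbol was repeated. The planned count-based tools were not run because the table holds no counts, and limma-voom on the recovered reads was run in their place. Genes near 1 TPM rest on few reads, since a read in a gene of 1 kb was worth up to 0.208 TPM (0.0958 TPM in the deepest library, Lgr5-enriched replicate 1).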

Other observations

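The genes in this part were named, and all tests in it chosen, after the results were seen. The goblet-enriched population expressed the maternally expressed non-coding RNAs of an imprinted locus on chromosome 12. Meg3 (109541001 to 109571726) stood at 37.8 ± 5.02 TPM (SD, n = 3) against 0.0994 ± 0.0244 in the Lgr5-enriched and 0.607 ± 0.0997 in the enterocyte-enriched population, and Rian (109603940 to 109661716) at 68.1 ± 22.5 against 0.116 ± 0.0783 and 0.881 ± 0.135 TPM. Dlk1 (109452823 to 109463336), the paternally expressed gene of the locus, was higher as well, at 8.25 ± 1.77 against 0.230 ± 0.185 TPM in the Lgr5-enriched population (log2 fold change 2.90, SE 0.24, limma adjusted p = 5.24e-05, no overlap between libraries). The acetylcholine receptor genes Chrm1 and Chrm3 and the short-chain fatty acid receptor gene Ffar2 stood highest in the same population, with no list of such receptors tested: Chrm1 stood at 19.2 ± 3.13 TPM against 2.97 ± 1.51 and 2.67 ± 0.505, Chrm3 at 11.9 ± 3.41 against 1.42 ± 1.03 and 0.598 ± 0.251, and Ffar2 at 95.6 ± 17.4 against 2.93 ± 0.995 and 7.66 ± 3.07 TPM. The chemokine Ccl6 reached 2018 ± 411 TPM there, against 24.4 ± 10.7 and 512 ± 139 TPM.

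Some metabolic genes stood highest in the Lgr5-enriched population, with no list of their pathways tested. Shmt1 stood at 184 ± 32.8 TPM against 50.7 ± 12.2 in the goblet-enriched and 60.7 ± 18.5 in the enterocyte-enriched population, Mthfd1 at 157 ± 30.96 against 48.2 ± 14.4 and 53.7 ± 13.8, and Gclm, a subunit of the enzyme that starts glutathione synthesis, at 132 ± 17.99 against 47.9 ± 1.57 and 55.3 ± 5.65 TPM (goblet-enriched against Lgr5-enriched log2 fold change -1.43, SE 0.13, limma adjusted p = 0.000114, no overlap between libraries). Cd74 and Reg3b were higher in replicate 1 of each population than in all libraries of replicates 2 and 3: Cd74 stood at 2811, 1095 and 3094 TPM in the libraries labelled replicate 1 of the Lgr5-enriched, goblet-enriched and enterocyte-enriched populations and at 48.6 to 370 TPM in the other 6. Reg3b stood at 2607, 97.7 and 796 TPM in the former and 1.75 to 38.8 TPM in the latter.

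The library labelled enterocyte-enriched replicate 1 had Y-linked transcripts and next to no Xist, although its label says female. A mixture of cells from female and male animals would keep Xist at a share of the level elsewhere, and Xist was 0.0965% of its mean in the other 2 enterocyte-enriched libraries. X-linked Kdm6a and Eif2s3x stood at 18.57 and 43.5 TPM there (at least 32 and 80.38 elsewhere). How male RNA came under this female label was not tested.

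Goblet cell transcripts were abundant in the enterocyte-enriched libraries: 17 goblet markers called higher there than in the Lgr5-enriched population stood at a median of 25.9%, 21.8% and 28.6% of the level in the goblet-enriched library of the same number. Carry-over of cells of the goblet-enriched population would bring all abundant transcripts at about 1 share. Among 74 genes at least 16-fold higher in the goblet-enriched than in the Lgr5-enriched population and at 20 TPM or more, 18 stood below 0.5 of that share in all 3 pairs (Meg3 at 1.47%, 1.26% and 2.23%, B3gnt6 at 2.11%, 1.44% and 2.92%), which argues against such carry-over as the whole source. A candidate explanation is goblet cells of another state inside the enterocyte gate: 2 markers, Zg16 and Tff3, were higher in the enterocyte-enriched library in all 3 pairs. Bulk libraries cannot show whether goblet cells or enterocytes held these transcripts, so the 2 cannot be told apart here.

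Goblet-enriched replicate 3 held colonocyte transcripts that stood far lower in the other goblet-enriched libraries. Over 32 genes with a mean of 50 TPM or more in the enterocyte-enriched population and a mean of goblet-enriched replicates 1 and 2 of at most 1% of it, the median level in goblet-enriched replicate 3 was 5.46% of that in enterocyte-enriched replicate 3, with quartiles of 4.878% and 6.323%. RNA or cells of the enterocyte-enriched population in this library would give such a near-constant share, and gene-by-gene regulation would spread it. Free RNA, sorted cells and misassigned reads were not separated, and no biological explanation was tested.

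Other splits of the same libraries were counted for each reported number of genes. The 6 libraries of a comparison can be split in 10 ways, too few for a share under 0.05. The real split gave 4423, 6396 and 5687 genes for goblet-enriched against Lgr5-enriched, enterocyte-enriched against Lgr5-enriched and goblet-enriched against enterocyte-enriched, the highest other split gave 1, 1 and 0, and 1 split, the real one, was as large in each. For all 9 libraries 100 splits were drawn, and 1, the real one, gave as many genes differing among the 3 populations (8136, highest other 3002). That share, 1 in 100, is the lowest that this number of splits can give. For genes highest in the Lgr5-enriched, goblet-enriched and enterocyte-enriched populations (499, 576 and 511) 1 split was as large in each, the real one. The highest other value was 497, from a split that kept the 3 goblet-enriched libraries together and mixed the others, so it counts genes of a real population. The Lgr5-enriched and enterocyte-enriched counts lie close to it, and the former was 224 under median-of-ratios scaling. No weight is put on either margin. These splits ignore the replicate numbers, which pair the samples. Among the 36 splits that part all same-number libraries, as the real one does, 1, the real one, was as large for each of the 4 counts. The highest other was 1811 genes differing among the 3 populations (1019 with a replicate block, against 9761) and 474 genes highest in a population.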
